A study of Mus musculus with 4 samples.

How the data were processed

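The series holds 4 arrays of mouse MC3T3-E1 cells, 1 for each combination of normal or osteogenic medium with 3 or 6 days of culture. Per the labels' protocols, RNA was purified on a silica column with DNase treatment, its integrity was checked on a Bioanalyzer, and biotin-labelled cRNA was made with a 3′ in vitro transcription kit and hybridised to Affymetrix Mouse Genome 430 2.0 arrays. The authors deposited 1 intensity per probe set and array on a linear scale, with no detection calls in the table used here. Each array's deposited intensity had a mean of 500 after its lowest and highest 2% of probe sets were left out, so the arrays had been scaled to each other before deposit. The software and the method that turned probes into probe set values are not given in the sources used here. Scaling every array to 1 mean removes any difference in total RNA per cell.

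The table had 45101 probe sets, of which 64 were controls. Gene names came from GEO's annotation of the array and were matched by Entrez ID to NCBI RefSeq names of assembly GRCm38.p6, used for names alone. Of the other probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none in the table used here. Of the former, 34741 matched by Entrez ID and 0 symbols were updated. Probe sets with several or no symbols entered no gene count. This left 18193 genes, 12467 of them measured in at least 1 comparison. No coordinates are given because the files name no genome build.

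Each array was shifted to a common 75th percentile over probe sets that were not controls, by factors of 1.003, 1.02, 0.988 and 0.991. Values below the pooled 50th percentile, a signal of 57.8, were then set to that floor, which stands in for the missing detection calls, and log2 was taken. A gene was represented by its probe set with the highest mean, and counted as measured in a comparison if above the floor on at least 1 of its 2 arrays. A gene at the floor on 1 side has only a bound, written "at least". Genes were counted as higher or lower at 2-fold, an absolute log2 difference of 1. With 1 array per group no p-value was computed for these differences. The medium was tested over both days, in an additive fit of medium and day with t-tests and Benjamini-Hochberg adjustment, once with each gene's own residual variance and once with variances moderated by empirical Bayes. This test was chosen after the data were examined, and its residual also holds any change of the medium difference between days. Agreement between probe sets was taken as the share of genes past 2-fold whose next brightest measured probe set had the same sign, with Wilson 95% intervals.

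For 27 gene lists with 641 entries, fixed before the data were examined, the median log2 difference of the measured members was set against 10000 random lists of the same size, drawn from 20 bins of mean expression. A list is called outside the random range below the 2.5th or above the 97.5th percentile. In the 5 comparisons this held for 16, 11, 9, 16 and 13 lists, where 1.35 of 27 would lie outside if genes varied independently. The random lists ignore that genes of a list may vary together. More lists could thus lie outside between single cultures without any effect of medium or day. Bootstrap intervals over list members used 1000 draws, and describe the spread of genes, not of cultures. A further 5 lists, on immediate-early genes, glucose-responsive arrestins, endoplasmic reticulum chaperones, aldehyde and drug oxidation enzymes, and keratin and epidermal genes, were drawn up after the data were seen.

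Genes named in the text followed a rule written before the data were examined. It took the 8 highest and 8 lowest genes of each medium comparison and the 5 highest and 5 lowest of each other comparison, leaving out clone names and genes whose measured probe sets disagreed in sign. It added up to 4 members of each list with the largest differences between media, and 10 osteoblast genes, of which 7 are reported here. The rule named 144 genes. Where 5 or fewer members of a list passed 2-fold, those outside the rule were named after their values were seen.

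The steps were tested on simulated arrays built from the normal medium arrays, whose spread between days was taken as noise, with 100 genes altered by each of 2 known amounts. These arrays were noisier than their source, with 2.37% of unchanged genes past 2-fold at day 3 against 1.46% between the normal medium arrays. The altered genes were drawn only from those with a mean signal more than 2-fold above the floor, so recovery of dimmer genes was not tested. At day 3, 96 of 100 genes altered 2.83-fold and 98 of 100 altered 8-fold were recovered among 12017 measured genes. At day 6, 95 of 100 and 99 of 100 were recovered among 12002.

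Alternatives were no further scaling, a shift to a common median, quantile normalization, floors at the 40th and 60th percentile, a pseudocount in place of the floor, neither floor nor filter, a stricter filter, the mean of a gene's probe sets, probe sets specific to 1 gene alone, and rules of 1.5-fold and 3-fold. A floor at the 80th percentile was added later. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.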

Results

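MC3T3-E1 is a preosteoblast line from the skull cap of newborn mice that lays down mineralised matrix when given ascorbic acid and a phosphate donor. Total RNA was measured on 4 Affymetrix Mouse Genome 430 2.0 arrays, with 1 array per group. Cells grew for 3 or 6 days either in normal medium, MEM α with 10% fetal bovine serum, or in osteogenic medium, the same with beta-glycerophosphate at 10 mM and ascorbic acid 2-phosphate at 150 µM. The series set out to find genes tied to osteogenic differentiation, so the media were compared at each day, the days within each medium, and the medium difference between days. There were no replicates, so no difference at a single day or between days has a test or an error from biological spread, and "higher" or "lower" in a count means by 2-fold or more between 2 single arrays. Differences between probe sets of the same gene gave an estimated error for a single probe set. In the log2 medium difference it was 0.259 at day 3 and 0.241 at day 6, which covers probe error only. Pearson's r between arrays, across probe sets, ranged from 0.968 to 0.988. The number of arrays limits the precision of every value.

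At day 3, genes of bone mineralisation stood out in osteogenic medium. Ibsp, which encodes bone sialoprotein, a mineral-binding matrix protein, had a signal of 4468 in osteogenic against 386 in normal medium, 11.6-fold higher. Dmp1, a matrix phosphoprotein of osteocytes and dentin, was 6.02-fold higher, and Alpl, the alkaline phosphatase that releases phosphate for mineral growth, was 2.94-fold higher. Phex, an endopeptidase of osteoblasts and osteocytes, was at the floor in normal medium and at least 2.94-fold higher in osteogenic medium. Of 17 measured genes of the mineralisation list, 9 were higher and 0 lower, with a median log2 difference of 1.23 (95% bootstrap interval over genes 0.29 to 1.56), above all 10000 random lists matched on expression. That median was 0.80 with the stricter filter and 0.66 with the floor at the 80th percentile.

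Several genes outside that list had differences of similar size at day 3. Itm2a, which encodes a transmembrane protein, was 11.0-fold higher, Panx3, a channel protein of bone and cartilage cells, 7.70-fold, Ramp1, a receptor subunit for calcitonin gene-related peptide, 6.19-fold, and Sostdc1, a secreted BMP antagonist, 5.73-fold. Zdhhc14, a palmitoyltransferase, was at least 5.98-fold higher and Lgals7, a galectin of stratified epithelia, at least 5.95-fold, both from the floor in normal medium. On the lower side, Zdhhc12 was 6.43-fold lower, Krtap12-1 5.40-fold, the matrix glycoprotein gene Sned1 4.64-fold, the kinase gene Zap70 3.77-fold, the aldehyde dehydrogenase gene Aldh3a1 3.74-fold and the neurotrophin receptor gene Ngfr 3.74-fold. Krtap12-1 had a signal of 61.4 in osteogenic medium, close to the floor. Ly6g2 and the clock gene Cry2 were at the floor in osteogenic medium, at least 4.52-fold and 3.86-fold lower. Zdhhc12 had a signal of 421 in normal medium at day 3 and 64.8 to 69.2 on the other arrays, so its difference rests on 1 array. At day 6 Zdhhc12 (0.095), Zap70 (0.032), Cry2 (0.31) and Zdhhc14 (-0.80) did not keep their direction on the log2 scale, while the others named here did.

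The list of cholesterol and fatty acid synthesis, called cholesterol synthesis from here on, had 21 of 25 genes above and 4 below zero at day 3. Its median log2 difference was 0.60 (0.15 to 0.74), and Idi1 (1.31) and Cyp51 (1.13) passed 2-fold. Cell cycle genes had a median of 0.27 (0.21 to 0.36), with 31 of 40 above zero and 0 past 2-fold. Osteoblast transcription factors had a median of 0.27, with Dlx3 (1.46) and Fos (1.36) higher, Mef2c (-1.05, at the floor in osteogenic medium) lower, and Sp7, a master regulator of osteoblast formation, at 0.69. The osteocyte list had a median of 0.47, but -0.060 when a gene's probe sets were averaged; its 3 higher members were Dmp1, Phex and Tnfrsf11b (2.42), the decoy receptor that limits osteoclast formation. Of 11 osteoclast-regulating factors, Tnfrsf11b and Il33 (at least 2.49) were higher and Efnb2 (-1.04) lower, with a median of 0.0011.

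More structural matrix genes lay below than above zero at day 3. The collagen list had a median of -0.26 (-0.39 to -0.10), with 16 of 21 genes below zero, Col11a2 (1.24) and Col18a1 (1.03) higher and Col16a1 (-1.06) lower. Col1a1 and Col1a2, the chains of type I collagen, had signals of 52437 and 59628 in osteogenic medium, log2 differences of -0.21 and -0.26. The highest deposited signal on that array was 70590.5, and whether signals this bright still follow the amount of RNA was not tested. Non-collagenous matrix genes had a median of -0.33 (-0.47 to -0.088), with 21 of 30 below zero and 1 past 2-fold, Lum (1.08). Matrix proteases and inhibitors had a median of -0.38 (-0.47 to 0.034), or -0.20 with the floor at the 80th percentile. Of these, 14 of 21 lay below zero and 1 passed 2-fold, Adamts5 (-1.24). Collagen modification genes had a median of -0.033, inside the random range, with 14 of 25 below zero and Loxl1 (-1.28), which cross-links elastin and collagen, and Creb3l1 (-1.05) lower.

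The medians of the other lists at day 3 were -0.15 for endoplasmic reticulum folding, -0.21 for the amino acid and ATF4 response, -0.26 for hypoxia and glycolysis, -0.14 for oxidative stress genes, -0.26 for ascorbate-linked enzymes, -0.16 for IGF and FGF signalling, -0.18 for Wnt signalling, 0.068 for BMP and TGF-beta signalling, -0.13 for interferon response genes and 0.059 for chemokines. Markers of other cell types had medians of -0.17 (adipocyte), 0.060 (chondrocyte), -0.11 (smooth muscle), 0.13 (skeletal muscle), -0.063 (leukocyte) and 0.090 (endothelial), while the chondrocyte genes Cnmd and Col2a1 were 2.56-fold and 2.18-fold higher. The chondrocyte median became 0.59 with the stricter filter, and with neither floor nor filter the adipocyte median became 0.35 and the skeletal muscle median 0.70. Reference genes, a control list, had a median of -0.18, below the random range, but 0.10 with averaged probe sets. Of the lists outside that range at day 3, Wnt stayed outside in 4 of 11 settings, osteocyte genes and osteoblast transcription factors in 8, the ATF4, oxidative stress, IGF and reference lists in 9, and the folding, hypoxia and ascorbate-linked lists in 10.

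In all, 233 genes were higher and 184 lower in osteogenic medium at day 3, of 11835 measured. Another probe set of the same gene had the same sign for 121 of 144 such genes, 84.0% (Wilson 95% interval 77.2 to 89.1%), and itself passed 2-fold for 41 of them (28.5%). In simulated arrays with noise modelled on the normal medium arrays, 280 of 11817 genes left unaltered (2.37%) passed 2-fold, against 417 here, while between the normal medium arrays themselves 171 of 11723 (1.46%) did. The counts were 134 and 91 with the floor at the 60th percentile and 388 and 347 with it at the 40th.

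**Figure D1:**
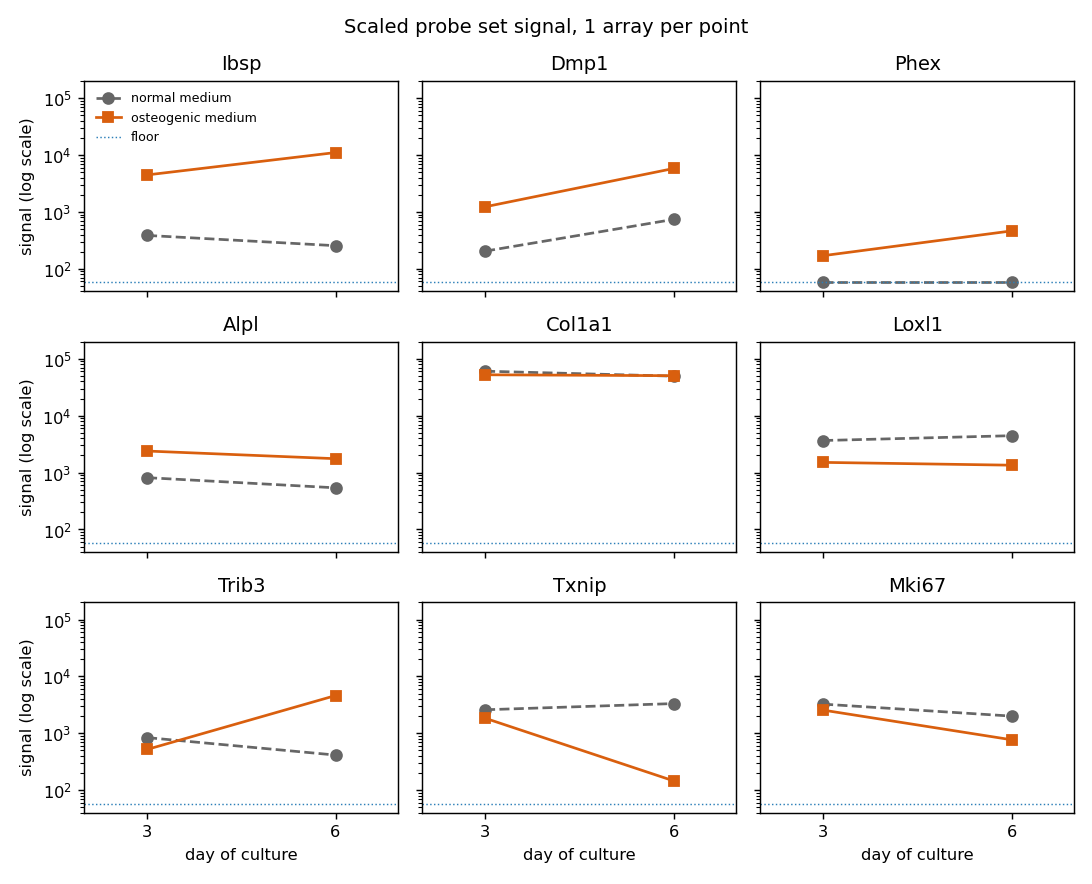
Scaled probe set signal (log scale) of 9 genes against day of culture in normal medium (grey circles) and osteogenic medium (orange squares), 1 array per point, with the floor dotted. Ibsp reached 11063 in osteogenic medium at day 6 against 255 in normal medium, while Col1a1 lay between 49645 and 60659 on all 4 arrays.

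At day 6 the mineralisation genes were again higher in osteogenic medium. Ibsp was 43.4-fold higher, with a signal of 11063 against 255, Dmp1 7.85-fold, Panx3 11.8-fold, Gpnmb 6.73-fold and Alpl 3.25-fold, and Phex was at least 8.01-fold higher. Of 19 measured mineralisation genes 11 were higher and 1, Cpz (-1.46, at the floor in osteogenic medium), lower, with a median log2 difference of 1.70 (0.088 to 2.34), or 0.79 with the floor at the 80th percentile. Prkg2, a cGMP-dependent protein kinase, went from 398 to 7968 (log2 difference 4.32) and the annexin gene Anxa8 was 17.4-fold higher. Klhl30 was 14.1-fold higher, from a signal of 64.0 in normal medium, close to the floor. Avil, which encodes an actin-binding protein, was at the floor in normal medium and at least 26.3-fold higher, as were Mlip (at least 11.6-fold) and the cartilage collagen gene Col11a2 (at least 11.2-fold).

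Txnip, an arrestin family member that limits glucose uptake, had the lowest ratio among the genes the naming rule takes at day 6, with a signal of 146 in osteogenic against 3328 in normal medium, 22.8-fold lower. Sned1 was 9.73-fold lower, Aldh3a1 6.86-fold, Tspan13 5.55-fold, the amine oxidase gene Aoc3 5.06-fold and Caprin2 4.83-fold. Astn1 and the matrix gene Abi3bp were at the floor in osteogenic medium, at least 5.51-fold and 5.25-fold lower.

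Genes of protein folding and amino acid stress were higher together at day 6. All 23 measured endoplasmic reticulum genes lay above zero and 10 were higher, with a median of 0.86 (0.58 to 1.29). Among them Ddit3, a stress-induced transcription factor, was 4.85-fold higher, Creld2 4.55-fold, Sdf2l1 3.70-fold and Atf3 3.60-fold. In the amino acid and ATF4 list 22 of 23 genes lay above zero and 10 were higher, with a median of 0.83 (0.50 to 1.17). Its Trib3, a pseudokinase induced by stress, was 11.1-fold higher, Chac1 4.05-fold, Slc6a9 2.97-fold and Aldh1l2 2.69-fold. Hypoxia and glycolysis genes had a median of 0.31 (0.086 to 0.62), and the 5 of 27 that were higher were Slc2a3 (1.63), Vegfa (1.56), Eno2 (1.49), Car9 (at least 2.84-fold) and the glucose transporter gene Slc2a1 (2.30-fold).

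Cell cycle genes were lower in osteogenic medium at day 6, with a median of -0.91 (-0.96 to -0.81). Of 39 measured, 37 lay below zero and 11 were lower, among them the replication licensing gene Cdc6 (-1.66), Rrm2 (-1.61), the proliferation marker Mki67 (-1.38) and the mitotic kinesin gene Kif11 (-1.25). Smooth muscle genes had a median of -0.38 (-0.91 to -0.044), with Lmod1 (-1.51) and Tpm1 (-1.06) lower and Des (at least 2.84-fold) higher.

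Of 13 osteoclast-regulating factors 8 were higher and 1, Efnb2 (-1.42), lower at day 6, with a median of 1.096 that became 0.20 with the floor at the 80th percentile. Examples were Ptgs2, the inducible cyclooxygenase (2.65), Il33 (2.36), Tnfrsf11b (2.19) and Lif (1.65). In the IGF and FGF list 6 of 21 were higher, among them Etv4 (at least 2.80), Igfbp2 (2.77), Dusp6 (2.13) and Igf2 (2.09), 3 were lower, Igf1 (-1.98), Fgf18 (-1.18) and Ghr (-1.09), and the median was 0.078. In the BMP and TGF-beta list 7 of 24 were higher, among them the BMP target genes Id3 (2.06) and Id1 (1.55), Ltbp2 (2.04) and Tgfb1 (1.71), with a median of 0.034. Osteoblast transcription factors had a median of 0.51, or 0.17 with the floor at the 80th percentile, with Fosl1 (at least 2.78), Lef1 (1.60) and Dlx3 (1.54) higher and Sp7 at 0.38.

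Matrix genes divided at day 6. Among 31 non-collagenous matrix genes, with a median of -0.34 (-0.56 to 0.097), 5 were higher, namely Tnc (2.12), Tgfbi (2.05), Eln (at least 1.75), Vcan (1.41) and Smoc2 (1.22), and 6 were lower, among them Ogn (-1.83). Among 21 collagen genes Col11a2, Col18a1 (2.26) and Col24a1 (1.02) were higher and Col8a1 (-1.35) and Col27a1 (-1.01) lower, and their median was 0.013, or -0.071 after quantile normalization. Col1a1 and Col1a2 had log2 differences of 0.03 and 0.07, again with signals near the top of the arrays' range. Collagen modification genes had a median of -0.19, outside the random range in 8 of 11 settings, with P4ha2 (1.34) higher and Pcolce2 (-1.81) and Loxl1 (-1.72) lower. Among 23 proteases and inhibitors, with a median of 0.18 (-0.47 to 0.58) that stayed outside the random range in 5 of 11 settings, Timp1 (1.67), Timp3 (1.27) and Plaur (1.24) were higher and Adamts1 (-1.67), Htra1 (-1.45), Mmp9 (-1.07) and Mmp16 (-1.05) lower.

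The other medians at day 6 were -0.025 for cholesterol synthesis, 0.17 for Wnt signalling, 0.21 for osteocyte genes, 0.077 for interferon response genes, 0.21 for chemokines, 0.11 for oxidative stress genes and -0.11 for ascorbate-linked enzymes. For markers of other cell types they were -0.25 (adipocyte), 0.045 (chondrocyte), 0.0069 (skeletal muscle), 0.090 (leukocyte) and 0.53 (endothelial), and for reference genes -0.019. The chondrocyte median became 0.77 with the stricter filter and 1.33 with the floor at the 80th percentile, and the adipocyte median 0.30 with that floor and 0.51 with neither floor nor filter. Of chondrocyte genes, Col2a1 was 4.84-fold and Cnmd 2.51-fold higher, while Sox6 was at -0.63.

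In all, 488 genes were higher and 330 lower at day 6, of 11888 measured, against 281 of 11802 unaltered genes past 2-fold in the simulated arrays. All comparisons with the osteogenic day 6 array, the time comparison in osteogenic medium and the change between days included, rest on an array whose control signal for the 5′ end of small-subunit ribosomal RNA was 746, against 5202 to 9162 on the other arrays. Another probe set had the same sign for 312 of 344 genes past 2-fold, 90.7% (87.2 to 93.3%), and itself passed 2-fold for 158 of them (45.9%).

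**Figure D2:**
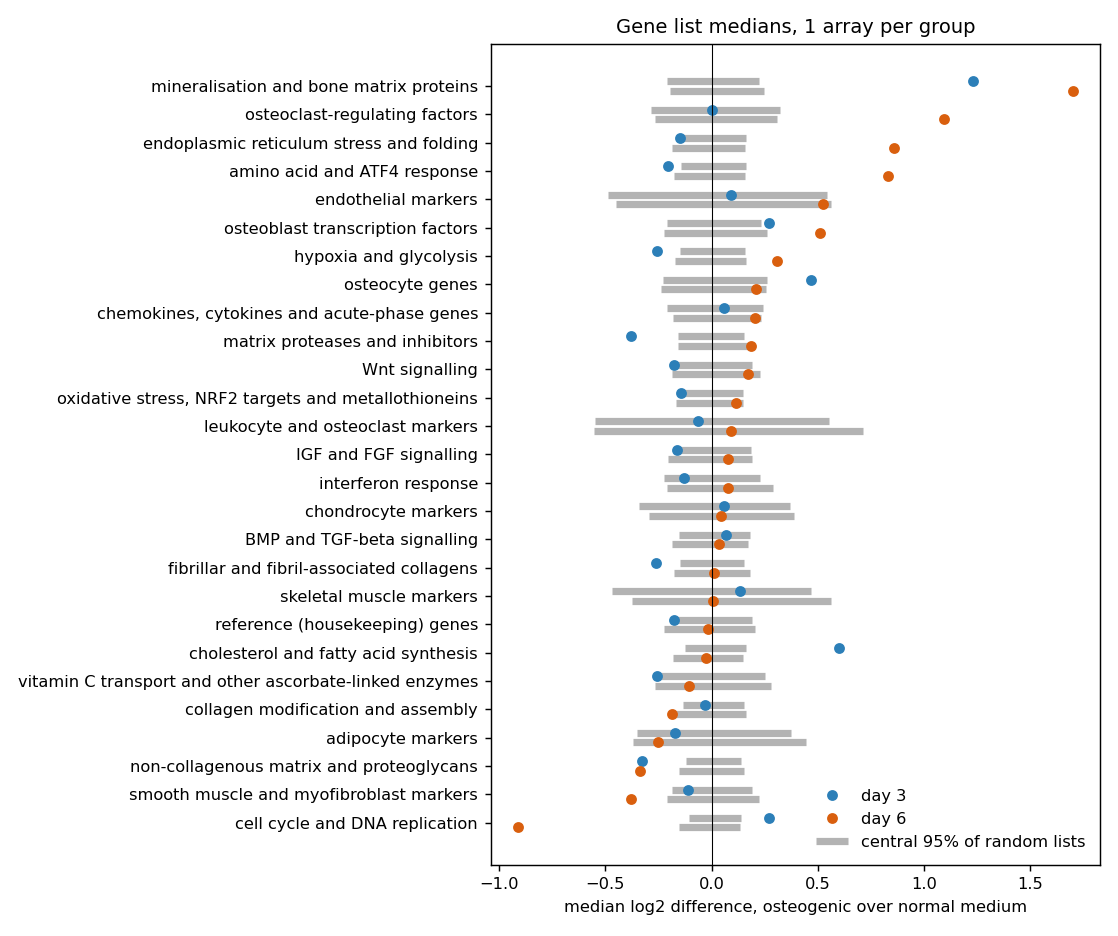
Median log2 difference, osteogenic over normal medium, of the 27 gene lists at day 3 (blue) and day 6 (orange), 1 array per group. Grey bars give the central 95% of medians of 10000 random lists matched on expression. The mineralisation list had medians of 1.23 and 1.70, and the cell cycle list 0.27 and -0.91.

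The medium differences of the separate pairs of arrays at day 3 and day 6 shared many genes. Ibsp, Dmp1, Panx3, Itm2a, Alpl and Igfbp2 were among 90 genes higher at both days, where independent lists would share 9.26. Sned1, Aldh3a1, Ngfr and Loxl1 were among 50 genes lower at both days, where independent lists would share 5.07. By contrast 4 genes were higher at day 3 and lower at day 6, and 4 the reverse, against 6.56 and 7.15 for independent lists. Among genes past 2-fold at day 3, 312 of 404 had the same sign at day 6, 77.2% (72.9 to 81.0%). Across 11256 genes, which are not independent replicates, Pearson's r between the day 3 and day 6 differences was 0.40 and Spearman's rho 0.35, and r was 0.057 with neither floor nor filter. In a fit of medium and day to all 4 arrays, with 1 residual degree of freedom, 0 of 11256 genes passed a false discovery rate of 5% for the medium (lowest adjusted p 0.196, or 0.165 with moderated variances).

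**Figure D3:**
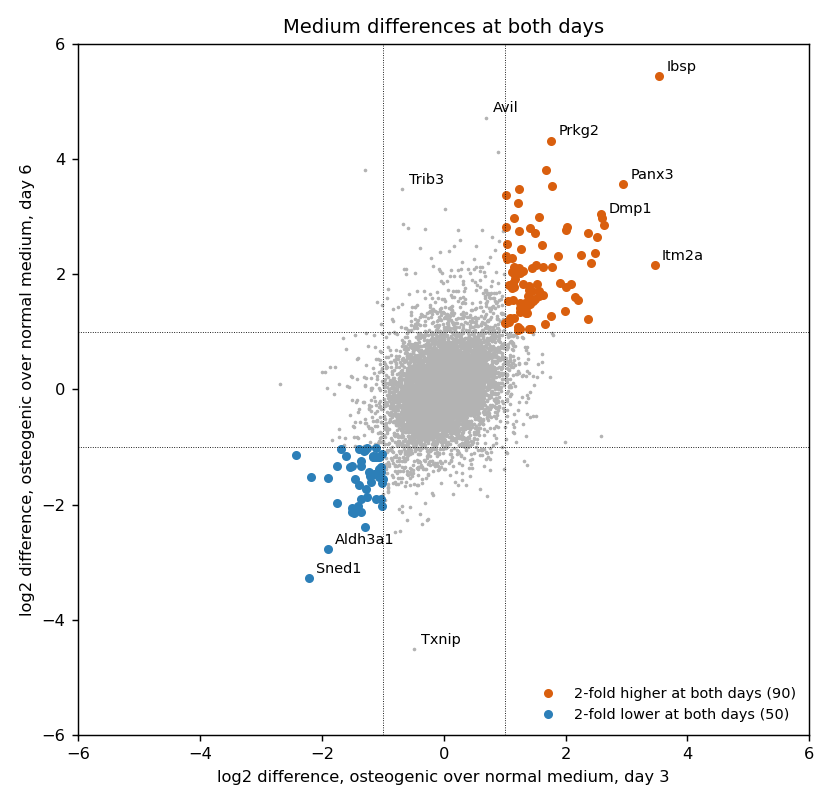
Log2 medium difference (osteogenic over normal medium) at day 3 against day 6 for 11256 genes, 1 array per group. Orange points mark the 90 genes 2-fold higher at both days, blue points the 50 genes 2-fold lower at both days, and dotted lines a 2-fold difference. Ibsp lies at 3.53 and 5.44, Sned1 at -2.21 and -3.28, and Txnip at -0.49 and -4.51.

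In normal medium, few genes differed between day 6 and day 3. Immediate-early genes, which respond within minutes to serum or stress, led the higher side at day 6 by the naming rule. Their log2 differences were 3.70 for Fos, 2.73 for Ier2, 2.01 for Egr1 and 1.90 for Dusp1. Dmp1 was higher at day 6 by 1.85 even without osteogenic supplements, from a signal of 204 to 739. Zdhhc12 (-2.70) was lower, which rests on the same day 3 value as its difference between media. Dbil5, Fosl1, Fitm1 and Lypd9 were at the floor at day 6, with bounds of -1.64, -1.62, -1.62 and -1.51. All 40 cell cycle genes lay below zero, with a median of -0.47 (-0.53 to -0.40), and 1 of them, Tyms, passed 2-fold with a bound of -1.14.

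Other lists outside the random range in normal medium were the amino acid and ATF4 response (-0.34), oxidative stress genes (-0.22), chemokines (0.39), interferon response genes (0.24), IGF and FGF signalling (0.19), endoplasmic reticulum folding (0.14), proteases (0.11) and collagen modification (0.077). Of these, chemokines stayed outside in 9 of 11 settings and the interferon and folding lists in 10. In total 87 genes were higher and 84 lower of 11723 measured, so 50.9% of these were higher, against 63.7% with arrays shifted to a common median. With the floor at the 60th percentile 36 were higher and 22 lower, and with it at the 40th 207 and 219. Another probe set had the same sign for 32 of 46 such genes, 69.6% (55.2 to 80.9%), and itself passed 2-fold for 5 of them (10.9%).

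In osteogenic medium, by contrast, 435 genes were higher and 312 lower at day 6 than at day 3, of 11925 measured, with a 5′ ribosomal RNA control signal of 746 on the day 6 and 8250 on the day 3 array. Cell cycle genes were lower throughout, with 32 of 40 past 2-fold and a median of -1.63 (-1.73 to -1.37). Cdc6 was at -2.45, Rrm2 at -2.17, Mki67 at -1.73 and the kinetochore gene Spc24, outside the list, at -2.46. Endoplasmic reticulum genes had a median of 1.23 (0.88 to 1.36), with 14 of 23 higher, and amino acid and ATF4 genes 0.65, with 5 of 23 higher, namely Trib3 (3.15), Chac1 (1.71), Aldh1l2 (2.78-fold), Slc6a9 (1.23) and Slc3a2 (1.11). The highest by the naming rule were Avil (3.17), Trib3, Car6 (at least 3.07), the semaphorin gene Sema7a (at least 3.07) and Fos (3.02). The lowest were Txnip (-3.66), Otor (-2.69), Pcolce2 (-2.64), Aldh1a7 (-2.56) and Spc24.

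Mineralisation genes divided between days within osteogenic medium, with a median of 0.35 (-0.062 to 0.94), 5 of 18 higher at day 6 and 6 below zero, among these Alpl (-0.45). Dmp1 was 4.72-fold, Gpnmb 4.05-fold, Phex 2.73-fold and Ibsp 2.48-fold higher. Other medians above the random range were 0.68 for osteoclast-regulating factors (-0.015 with the floor at the 80th percentile), 0.57 for hypoxia and glycolysis, 0.56 for IGF and FGF signalling, 0.43 for interferon response genes, 0.42 for osteoblast transcription factors (-0.070 with that higher floor), 0.36 for chemokines, 0.35 for oxidative stress genes, 0.34 for ascorbate-linked enzymes, 0.29 for proteases and 0.13 for collagens. The collagen list stayed above that range in 7 of 11 settings, the transcription factors in 8, the osteoclast-regulating, interferon and chemokine lists in 9 and the mineralisation list in 10. Cholesterol synthesis and smooth muscle genes both had medians of -0.58. Another probe set had the same sign for 267 of 304 genes past 2-fold, 87.8% (83.7 to 91.0%), and itself passed 2-fold for 138 of them (45.4%).

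The medium difference at day 6 exceeded that at day 3 by 2-fold or more for 542 genes and fell short of it by as much for 372, of 12467 measured. By the naming rule, the largest increases on the log2 scale were those of Trib3 (4.17), Avil (4.02), Sema7a (3.54), the epidermal gene Cdsn (3.38) and Anxa8 (3.23), and the largest decreases those of Txnip (-4.02), the smooth muscle gene Cnn1 (-2.89), Aldh1a7 (-2.67), Otor (-2.57) and Utf1 (-2.56). For Avil, Sema7a and Utf1 at least 1 of the 4 values was at the floor. Endoplasmic reticulum genes had a median change of 0.96, with 11 of 23 past 2-fold, and the amino acid and ATF4 list 0.99, also with 11 of 23. Cell cycle genes had a median change of -1.03, with 25 of 40 past 2-fold downward, and cholesterol synthesis genes -0.51. Other lists outside the random range were hypoxia and glycolysis (0.48), IGF and FGF signalling (0.44), oxidative stress (0.39), proteases (0.29) and smooth muscle (-0.49). Mineralisation (0.35), ascorbate-linked enzymes (0.30) and collagens (0.18) stayed outside in 9 of 11 settings, and endothelial markers (-0.46) in 3 of 10.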

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

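The tests of RNA intactness, amino acid shortage and glucose were chosen only after the results they bear on were seen, and the lists of immediate-early genes, chaperones and arrestins were drawn up on the same data. The differences between days listed next were not tested, since each group had 1 array. All comparisons with day 6 in osteogenic medium rest on the same array.

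Some gene groups lay outside the random range in opposite directions at day 3 and day 6. Cell cycle genes had a median medium difference of 0.27 at day 3 and -0.91 at day 6. The medians were -0.15 and 0.86 for endoplasmic reticulum folding genes, -0.21 and 0.83 for amino acid and ATF4 genes, -0.26 and 0.31 for hypoxia and glycolysis genes, and -0.38 and 0.18 for matrix proteases and inhibitors. The day 6 protease median had a bootstrap interval of -0.47 to 0.58 and stayed outside in 5 of 11 settings, the day 3 ATF4 median in 9, and the day 3 folding and hypoxia medians in 10. The reference genes, a control list, also lay below the range at day 3, with a median of -0.18.

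Single genes passed 2-fold in opposite directions at the 2 days, most of them named only because of this. There were 4 higher then lower and 4 the reverse, fewer than the 6.56 and 7.15 that independent lists would share. Aldh1a7, an aldehyde dehydrogenase gene, went from 1.36 at day 3 to -1.31 at day 6 on the log2 scale, Otor from 1.32 to -1.25, Kcnk4, a potassium channel gene, from 1.04 to -1.11, and Eme1, a DNA repair gene, from 1.02 to -1.09. In the other direction Fahd2a went from -1.29 to 3.81, with 1 of its 3 measured probe sets against it, Susd5 from -1.09 to 1.51, the phosphatase gene Inpp5j from -1.02 to 1.46 and Ptprn from -1.02 to 1.13. Eme1 at day 6, Fahd2a at day 3, and Ptprn and Susd5 at both days rest on a value at the floor. Kcnk4 at both days and Fahd2a at day 6 rest on a value close to the floor of 57.8. These were 59.8 for Kcnk4 in normal medium at day 3 and 60.7 in osteogenic medium at day 6. For Fahd2a the value was 58.0 in normal medium at day 6.

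Among probe sets with several gene names or none, which entered no comparison, 12 were higher and 19 lower in osteogenic medium at both days.

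More genes passed 2-fold between media at day 6 (818) than at day 3 (417). In 18837 probe sets below the floor on all arrays, the spread of differences at day 6 was 1.003 times that at day 3. These probe sets cannot show noise in genes above the floor, where the counted differences lie, so noisier arrays stay open for those genes. Errors of single probe sets as the whole cause are argued against by the 90.7% of genes whose other probe set had the same sign at day 6, although it passed 2-fold itself in only 45.9%. Less intact RNA stays open, because the ratio of 3′ to 5′ control signal was 1.05 times as high in osteogenic as in normal medium at day 6 for beta-actin and 0.993 times for Gapdh, but 6.05 times as high for small-subunit ribosomal RNA. A growing response to the medium, which may explain the difference, and chance differences between single cultures both stay open.

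Of the genes past 2-fold at day 3, 92 did not keep their sign at day 6. If signal error near the floor were the cause, dimmer genes would repeat less often, and they did. The genes were split at a signal of 275 on the brighter array. The dimmer 202 genes kept their sign in 71.3% (64.7 to 77.1%) and the brighter 202 in 83.2% (77.4 to 87.7%). Error near the floor is therefore a candidate explanation for part of the loss, and these intervals did not overlap. Genes that truly differ between media at day 3 alone stay open as the biological explanation.

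Folding and ATF4 response genes were higher in osteogenic medium at day 6. Amino acid shortage is taken to leave chaperones unchanged, and all 13 chaperones lay above zero with a median of 0.86 (0.50 to 1.37). The chaperones were listed after the folding genes were seen to be higher, with the same median. This is therefore no independent test, and amino acid shortage stays open, in whole or in part. Lower glucose at harvest may contribute, since the glucose-responsive genes Txnip (-4.51) and Arrdc4 (-1.38, a bound) were both more than 2-fold lower, but Txnip was known to be low when the test was chosen. Stress of handling at harvest cannot be told apart. The immediate-early genes had a median of 0.41 (0.13 to 0.64) at day 6, between what handling and its absence would give. However, in normal medium a median of 0.94 for these genes between days went with only 0.14 for folding genes. Between media at day 3, an immediate-early median of 0.59 went with -0.15 for folding genes and -0.21 for ATF4 genes. Each of these values compares single arrays. A direct effect of matrix secretion or mineral in osteogenic medium was not tested.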

How the results depend on the processing

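The floor at the pooled 80th percentile was chosen after the data were examined and the other settings before. Under the 3 scaling alternatives every count stayed within 1.5 times its main value, although some list medians moved. Of 7257 recomputed log2 differences of named genes over 11 settings, 6678 moved by no more than the error estimated for a single probe set. Another 577 moved further, and 2 changed sign from a 2-fold difference, both for Phex. Of 65 list medians outside the random range, 38 stayed outside under every setting run, among them the mineralisation list and the cell cycle list in both medium comparisons. Recomputed list medians moved by no more than their bootstrap SD 1362 times, further 92 times, and 9 times took the other sign where the list lay outside the random range. Signs of medians near zero also differed between settings, as given here. Counts depended on the floor, the filter and the fold rule, which by construction admit more or fewer dim or small differences. The causes of the moved medians were not tested. No replicate could be left out because each group had 1 array. With the days taken as pairs, a test of the medium over both days, added after the data were examined, had 1 residual degree of freedom and passed 0 genes. The mean of a gene's probe sets leaves no other probe set to compare. Signal over background limits the precision, since with neither floor nor filter the other probe sets of called genes had the same sign far less often. Shifting the arrays to a common median gave list medians -0.96 for cell cycle genes between media at day 6; 0.15 for collagen modification genes, 0.017 for non-collagenous matrix genes, 0.045 for BMP genes, -0.39 for cell cycle genes, 0.22 for endoplasmic reticulum genes, -0.039 for hypoxia genes, 0.019 for cholesterol genes, 0.31 for interferon genes, -0.15 for oxidative stress genes, -0.041 for smooth muscle genes and -0.067 for reference genes between days in normal medium; -1.11 for cell cycle genes for the change in the medium difference. Quantile normalization gave list medians -0.071 for collagen genes between media at day 6; 0.045 for non-collagenous matrix genes, -0.44 for cell cycle genes, -0.032 for smooth muscle genes and -0.053 for reference genes between days in normal medium; 0.051 for collagen genes for the change in the medium difference. With the floor at the pooled 40th percentile, the higher and lower counts were 388 and 347 between media at day 3, 207 and 219 between days in normal medium, 609 and 473 between days in osteogenic medium, 852 and 633 for the change in the medium difference and 122 and 77 at both days. The other probe sets of a gene then had the same sign for 72.1% between media at day 3, 82.0% between media at day 6 and 78.8% between days in osteogenic medium. This lower floor gave list medians 0.051 for adipocyte genes between media at day 3; 1.06 for ATF4 genes between media at day 6; 0.47 for protease genes and 0.65 for chemokine genes between days in osteogenic medium. With the floor at the pooled 60th percentile, the higher and lower counts were 134 and 91 between media at day 3, 36 and 22 between days in normal medium, 331 and 239 for the change in the medium difference and 59 and 37 at both days. The other probe sets of a gene then had the same sign for 97.6% between media at day 3, 98.4% between media at day 6, 94.7% between days in normal medium and 94.6% between days in osteogenic medium. Under that 60th percentile floor the list medians were 0.59 for chondrocyte genes between media at day 3; 0.77 for chondrocyte genes between media at day 6; 0.15 for chemokine genes and -0.31 for endothelial genes between days in normal medium; 0.49 for protease genes, 0.21 for interferon genes and 0.14 for chemokine genes between days in osteogenic medium; 0.17 for endothelial genes for the change in the medium difference. With a pseudocount in place of the floor, the higher and lower counts were 483 and 453 between media at day 3, 790 and 553 between media at day 6, 288 and 326 between days in normal medium, 726 and 572 between days in osteogenic medium, 1050 and 811 for the change in the medium difference and 123 and 89 at both days. The other probe sets of a gene then had the same sign for 87.0% between media at day 6. The pseudocount gave list medians 1.07 for ATF4 genes between media at day 6; 0.49 for protease genes and 0.64 for chemokine genes between days in osteogenic medium; 0.0081 for endothelial genes for the change in the medium difference. The value of Phex was then -1.65 for the change in the medium difference. With neither floor nor filter, the higher and lower counts were 2329 and 2084 between media at day 3, 2525 and 2195 between media at day 6, 2025 and 2018 between days in normal medium, 2383 and 2290 between days in osteogenic medium, 3044 and 2868 for the change in the medium difference and 706 and 562 at both days. The correlation across genes was then 0.057. The other probe sets of a gene then had the same sign for 56.6% between media at day 3, 62.9% between media at day 6, 51.4% between days in normal medium and 60.03% between days in osteogenic medium. Without floor and filter the list medians were 0.56 for osteoclast-regulating genes, 0.35 for adipocyte genes and 0.70 for skeletal muscle genes between media at day 3; 1.07 for ATF4 genes and 0.51 for adipocyte genes between media at day 6; 0.21 for osteocyte genes and 0.25 for adipocyte genes between days in normal medium; 0.51 for protease genes, 0.58 for chemokine genes and -0.21 for adipocyte genes between days in osteogenic medium; -0.23 for osteocyte genes, -0.48 for adipocyte genes and 0.029 for endothelial genes for the change in the medium difference. The value of Phex was then -3.60 for the change in the medium difference. With the stricter filter, the higher and lower counts were 158 and 115 between media at day 3, 51 and 38 between days in normal medium and 329 and 277 for the change in the medium difference. The other probe sets of a gene then had the same sign for 96.1% between media at day 3, 96.7% between media at day 6, 85.7% between days in normal medium and 94.9% between days in osteogenic medium. The stricter filter gave list medians 0.80 for mineralisation genes and 0.59 for chondrocyte genes between media at day 3; 0.77 for chondrocyte genes between media at day 6; -0.31 for endothelial genes between days in normal medium; 0.49 for protease genes between days in osteogenic medium. Taking the mean of a gene's probe sets gave list medians -0.060 for osteocyte genes, -0.18 for collagen modification genes, -0.055 for oxidative stress genes and 0.10 for reference genes between media at day 3; -0.14 for collagen genes and -0.80 for cell cycle genes between media at day 6; -0.11 for BMP genes, -0.44 for cell cycle genes, 0.038 for endoplasmic reticulum genes, -0.045 for hypoxia genes and -0.068 for reference genes between days in normal medium; 0.098 for osteoblast transcription factor genes, -1.49 for cell cycle genes and -0.44 for cholesterol genes between days in osteogenic medium; -0.67 for smooth muscle genes, 0.082 for endothelial genes and -0.15 for reference genes for the change in the medium difference. Gene-specific probe sets alone gave list medians -0.056 for smooth muscle genes between days in normal medium; 0.044 for endothelial genes for the change in the medium difference. At 1.5-fold, the higher and lower counts were 1000 and 844 between media at day 3, 1333 and 1089 between media at day 6, 475 and 444 between days in normal medium, 1273 and 1007 between days in osteogenic medium, 1493 and 1227 for the change in the medium difference and 376 and 262 at both days. At 3-fold, the higher and lower counts were 38 and 26 between media at day 3, 165 and 61 between media at day 6, 12 and 5 between days in normal medium, 97 and 99 between days in osteogenic medium, 139 and 75 for the change in the medium difference and 25 and 3 at both days. With the added floor at the pooled 80th percentile, the higher and lower counts were 33 and 20 between media at day 3, 126 and 95 between media at day 6, 12 and 2 between days in normal medium, 91 and 79 between days in osteogenic medium, 98 and 50 for the change in the medium difference and 16 and 12 at both days. List medians under the 80th percentile floor were 0.66 for mineralisation genes, -0.16 for collagen modification genes, -0.20 for protease genes, -0.11 for BMP genes, 0.051 for adipocyte genes and 0.59 for chondrocyte genes between media at day 3; 0.17 for osteoblast transcription factor genes, 0.79 for mineralisation genes, -0.068 for collagen genes, 0.20 for osteoclast-regulating genes, -0.70 for cell cycle genes, 0.30 for adipocyte genes and 1.33 for chondrocyte genes between media at day 6; -0.076 for osteoclast-regulating genes, 0.10 for interferon genes and 0.15 for chemokine genes between days in normal medium; -0.070 for osteoblast transcription factor genes, 0.74 for mineralisation genes, -0.015 for osteoclast-regulating genes, -1.06 for cell cycle genes, 0.44 for hypoxia genes, 0.072 for interferon genes, 0.091 for chemokine genes and -0.20 for adipocyte genes between days in osteogenic medium; 0.76 for mineralisation genes, -0.75 for cell cycle genes, -0.10 for interferon genes, -0.019 for chemokine genes and 0.23 for chondrocyte genes for the change in the medium difference.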

Other observations

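The gene groups described here were drawn up after the data were seen. Immediate-early genes were higher at day 6 than at day 3 in both media, with a median log2 difference of 0.94 (0.61 to 1.67) in normal and 0.91 (0.64 to 1.47) in osteogenic medium, and 10 of 21 genes past 2-fold upward in each. Fos went from 274 to 3545 in normal and from 700 to 5662 in osteogenic medium, and Egr1 from 4902 to 19788 and from 9237 to 20323. Fosl1 differed between media, at -1.62 (a bound) in normal and 1.47 in osteogenic medium. Between media the median was 0.59 at day 3, with 20 of 21 above zero.

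Several epithelial and keratinocyte genes were higher in osteogenic medium. Of 7 measured at day 3, 4 were higher, namely Lgals7 (at least 2.57), Krt23 (at least 2.08), the cadherin gene Cdh3 (at least 2.00) and Krt14 (1.44), and of 6 measured at day 6, 5 were higher, the same 4 genes at 3.04, 1.82, 1.77 (a bound) and 2.11 together with Cdsn (2.80). The medians were 1.44 (-0.014 to 2.08) and 1.96 (0.92 to 2.92). At day 3, 2 of the 7 lay below zero, among them Cdsn (-0.58). Genes of aldehyde and drug oxidation had a median of -0.75 (-1.39 to -0.11) over 12 genes at day 6, with 9 below and 3 above zero. Of these Aldh3a1 (-2.78), Aoc3 (-2.34), Aldh1a1 (-1.48) and Aldh1a7 (-1.31) were lower, while at day 3 their median was 0.083 (-0.95 to 0.21), with 3 of 13 lower and 1 higher.

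The control probe set for the 5′ end of small-subunit ribosomal RNA had a signal of 9162 in normal medium at day 3, 8250 in osteogenic medium at day 3, 5202 in normal medium at day 6 and 746 in osteogenic medium at day 6. The control for its middle part had 994, 784, 807 and 409 in that order, and that for its 3′ end 303, 273, 267 and 232. The ratio of 3′ to 5′ signal was between 1.17 and 1.25 for beta-actin and between 0.756 and 0.769 for Gapdh on the 4 arrays.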
